A study of Mus musculus with 10 samples.

How the data were processed

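The series holds 5 single-cell RNA libraries and 5 BCR V(D)J libraries from the spleens of 3 BXD2-p19-/- mice and 2 BXD2 WT mice, made with the 10x 5' kit, 1 of each kind per mouse. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0.2 and STAR against mm10. For each RNA library the authors deposited a matrix of raw UMI counts per gene and cell barcode, not normalized, with other text giving the barcodes and gene names. The deposited matrices hold barcodes the authors had already filtered, and their values were checked to be whole numbers. For each BCR library the authors deposited an annotated contig table with read and UMI counts, V, D, J and constant gene calls, CDR3 sequences and a clonotype number. The mouse was the unit of replication throughout, and sex came from the labels (p19-/- 3 is male). The labels give no capture or sequencing day, so batches could not be examined, and they describe no sort or gate beyond naming B and T cells and, in the series design, GC B cells.

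The 5 RNA libraries held 11355 barcodes and 69958493 UMIs. Barcodes with over 10% mitochondrial UMIs (1907, or 16.8%) or under 200 genes were removed, and of the 9356 that passed, 156 (1.67%) were removed as doublets by Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells, leaving 9200 cells. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen, and 20 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15) gave 26 clusters. Immunoglobulin and T cell receptor genes, Xist, Tsix and Y-linked genes were left out of the clustering, as were the lists for switching machinery, base excision repair, cytokine receptors and zone-tested genes, so that these could be compared between groups. No batch correction was applied.

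Clusters were named only from marker lists fixed in advance, by a lineage score and the markers among the 10 leading genes: GC B, mature non-GC B, plasma cell, CD4 T, CD8 T, Tfh, Treg, macrophage or monocyte, dendritic cell, neutrophil and erythroid each named at least 1 cluster. The lists for marginal zone, transitional and memory or age-associated B cells, naive T, NK, platelet and stromal cells named none, although memory or age-associated markers (Ccr6, Hhex, Zbtb32) were among the leading genes of the mature non-GC B clusters. Clusters 9 and 20 stayed unnamed B (384 cells), cluster 7 unnamed T (480 cells) and cluster 16 unnamed (119 cells). Clusters with a median under 0.3333 of their samples' median UMIs were set aside as low-UMI (364 B and 79 T cells). This was done only where none of the markers of their class was among the 10 leading genes. CD4 T-like cells pooled the Tfh, Treg and other CD4 T clusters, so these comparisons share cells.

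For each class, UMI counts were summed per mouse and compared between genotypes in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, at 0.05. A fold change is p19-/- over WT, and its SE was taken from the fold change and the F statistic. A class-by-genotype interaction between GC B-like and mature non-GC B-like cells was fitted with mouse as a block. Gene lists with at least 5 tested members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a class. For zones, GC B-like cells were ranked within each mouse by a score of dark minus light zone genes, whose own genes were left out of the test, and the 0.3333 of cells at each end were summed per mouse and compared with mouse as a block. Shares of cells were compared by a two-sided exact permutation test over the 10 splits of 3 against 2 mice, with Clopper-Pearson 95% intervals per mouse and a floor of 3 counts for values of 0.

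The 27 gene lists, the marker lists, the 25 key genes, the comparisons and the main settings were fixed before the data were examined, apart from the Treg-like class, the comparison of the unnamed T cluster, the clustering without the genes that had been called and the B cell share without the unnamed clusters, which were added after. The lists cover switching machinery, base excision repair, cytokine receptors of B cells, dark zone, light zone, S phase, G2 and M phase, type I interferon response, interferon gamma response, NF-kB and IL-17 response, memory B, plasma cell, MHC class II presentation, B cell receptor signalling, oxidative phosphorylation, glycolysis, immediate early and heat shock, Th17, Th1, Tfh, Treg, naive T, T cell activation and exhaustion, and markers of T, B, myeloid and erythroid cells. The naming rule took, per class, genes with adjusted p under 0.05, no overlap between the 3 and 2 libraries and a mean of at least 10 CPM, up to 10 per direction by fold change. It left out immunoglobulin and T cell receptor segments, sex-linked marker genes, unnamed models and mitochondrial and ribosomal protein genes. It added up to 4 members per described list by smallest p, the key genes and the zone-tested genes, whatever their p. Lag3 in both T cell classes, Hba-a1 in CD4 T-like cells, Hspa8 and Hsp90aa1 came from the lists or the naming rule. The cells that held globin UMIs were counted after those calls were seen. Il23a and Il23r had too few counts to be tested in GC B-like cells. A few single-gene results are not reported here.

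BCR contigs were used when productive, of high confidence and with a constant gene, and the heavy chain with the most UMIs was taken per barcode and joined to the RNA library of the same mouse. The libraries p19-/- 1 to 3 and WT 1 and 2 held 821, 355, 1152, 1189 and 586 barcodes with a heavy chain. A clone was a set of cells with the same heavy chain V gene, J gene and CDR3 nucleotides, and the expanded share was the mean of 100 draws of 160 GC B-like cells per mouse.

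Alternatives were DESeq2 size factors, DESeq2 1.42.0's Wald test, no filter on low counts, sex as a covariate, the label number as a block, no immunoglobulin genes in scaling, doublets kept, stricter cell limits (5% mitochondrial UMIs, 500 genes), Leiden resolution 0.6, leaving out each mouse, camera with an estimated correlation and fry. For zones they were 0.5 of the cells at each end, a dark score with cell cycle genes and cells thinned to 2000 UMIs before scoring. Cells with fewer UMIs were left out of the last. For BCR shares they were each clone counted once, all cells, isotype from RNA, cells with exactly 1 heavy chain, the authors' clonotype number and no equal draw. Coordinates are those of the mm10 annotation. Random sets of genes for a layout test were drawn 10000 times, with a reach of 2000000 bases and neighbours within 100000 bases merged.

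The gene test was also tested on simulated data, with 200 genes changed in counts drawn to match each class. At 1.5-, 2- and 4-fold it recovered 13.4%, 59.7% and 93.9% in GC B-like, 1.49%, 10.4% and 86.4% in mature non-GC B-like, 29.9%, 56.7% and 93.9% in CD4 T-like and 25.4%, 61.2% and 86.4% in Tfh-like cells, each with the right sign. Unchanged genes were 6.72%, 11.0%, 4.76% and 9.45% of those called. Changes of 1.5-fold were thus mostly missed at this number of mice. The adjustment is stricter where fewer genes change, so with fewer changed genes than simulated the recovery may be lower. Light chains, T cell receptor sequences and hypermutation of V genes were not analysed here.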

Results

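Splenic B and T cells of BXD2 mice, a recombinant inbred strain that spontaneously forms germinal centers (GCs) and autoantibodies, were profiled by droplet single-cell RNA sequencing and B cell receptor (BCR) V(D)J sequencing. The groups were 3 mice lacking the p19 subunit of the cytokine IL-23 (p19-/-; 2 females and 1 male) and 2 female wild-type (WT) mice, with 1 RNA and 1 BCR library each. The series title ties IL-23 to class-switch recombination toward IgG2b, so GC B cells, their helper T cells and their isotypes were compared between the genotypes. The RNA libraries p19-/- 1 to 3 and WT 1 and 2 held 2474, 1104, 2595, 3226 and 1956 barcodes and 11433829, 7712457, 18093053, 17331992 and 15387162 UMIs. After filtering, 1547, 944, 2310, 2729 and 1670 cells remained, with medians of 3892, 4984, 4658, 3876 and 5231 UMIs. Values are means ± SD over mice, and cell classes are called "-like" because clusters of marker genes, not sorted populations, define them.

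Il23a, which encodes p19, gave 0 UMIs in each of the 5 RNA libraries, so the knockout could not be checked from RNA. A floor of 3 counts corresponds to 0.262, 0.389, 0.166, 0.173 and 0.195 CPM, counts scaled to a common library total, in the 5 libraries. Il23r, the receptor subunit specific to IL-23, gave 7, 4 and 9 UMIs in the p19-/- libraries and 6 and 14 in the WT libraries. Il17a, the cytokine most closely associated with IL-23-driven T cells, gave 0, 0 and 1 against 2 and 0 UMIs, and its level could not be compared at this depth. Ddx3y, a Y-linked gene, was seen in p19-/- 3 alone (1008 UMIs), and Xist gave 10 UMIs there and 4744 to 12082 in the other 4, matching the labelled sexes.

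GC B-like cells were the largest class, with 2899 of 9200 cells, followed by T follicular helper (Tfh)-like cells (1871), regulatory T (Treg)-like cells (961) and mature non-GC B-like cells (640). GC B-like cells made up 14.6%, 25.8% and 38.5% of cells in the p19-/- mice and 39.0% and 28.4% in the WT mice (26.3 ± 12.0% against 33.7 ± 7.53%, two-sided exact permutation p = 0.4). Tfh-like shares were 20.5 ± 3.79% and 22.0 ± 5.19% (exact permutation p = 0.8). Other CD4 T-like cells were the class with the lowest p among those named, 2.03 ± 0.585% against 3.26 ± 0.465% (exact permutation p = 0.2, 0.914 after Benjamini-Hochberg adjustment over 16 classes). With 3 mice against 2 there are 10 splits, and 0.2 is the smallest two-sided p this design allows, so it cannot reach 0.05. Among B cells, the GC B-like share was 58.2 ± 19.5% against 75.9 ± 7.08% (exact permutation p = 0.4). The difference of -17.6 percentage points went to -3.25 when 2 unnamed B clusters, which held 298 cells of p19-/- 1 and 61 of p19-/- 2, were left out; without p19-/- 1 it was -6.53. The labels describe no sort or gate, so how far these shares are those of the spleen is not known.

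**Figure D1:**
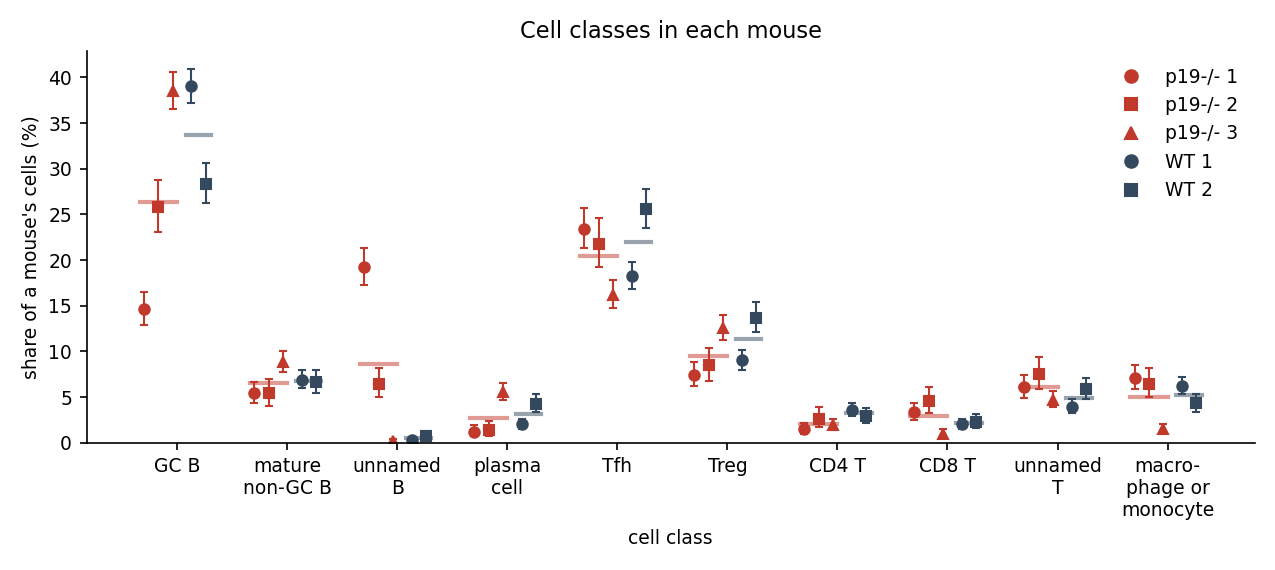
Share of each mouse's cells (%, vertical axis) in 10 cell classes (horizontal axis), with p19-/- mice in red and WT mice in blue-grey; bars on points are Clopper-Pearson 95% intervals and cover counting error only, and short lines are group means. GC B shares of p19-/- 3 (38.5%) and WT 1 (39.0%) are close together, and the unnamed B class stands out in p19-/- 1 (19.3%).

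In GC B-like cells, 2 of 10481 genes differed between p19-/- and WT mice. Stab2, a scavenger receptor for hyaluronan that is normally a gene of sinusoidal endothelium (chromosome 10, 86841194 to 87008038), was at 0 UMIs in the 3 p19-/- mice and at 302 and 205 UMIs in WT, 27.9 ± 2.2 CPM. Against a floor of 3 counts over the group it was at least 167-fold lower in p19-/- (adjusted p = 0.00411, edgeR quasi-likelihood test). Ulbp1, a stress-induced ligand of the NK cell receptor NKG2D (chromosome 10, 7444873 to 7473641), was higher, at 30.1 ± 1.67 against 9.57 ± 0.442 CPM (log2 fold change 1.66, SE 0.132, adjusted p = 0.0106). For both genes the 3 p19-/- libraries did not overlap the 2 WT libraries, which chance gives for 20% of genes. At an unadjusted p under 0.05, 872 genes passed, and DESeq2's Wald test called 48. Without WT 1 or WT 2 no gene was called; without p19-/- 1, 2 or 3 there were 10, 4 and 9.

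None of the 23 tested genes that had been fixed as key to switching, repair and isotype passed in GC B-like cells, with edgeR adjusted p from 0.515 to 1.00. Neil1, a DNA glycosylase that starts base excision repair, came closest at 322 ± 56.1 CPM in p19-/- against 433 ± 5.15 in WT (log2 fold change -0.43). Ighg2b, the IgG2b constant gene, stood at 173 ± 77.2 against 195 ± 40.0 CPM (-0.18, adjusted p = 0.889). Other fold changes were -0.45 for Ighg2c, 0.43 for Ighg1, -1.41 for Igha, 0.14 for Ung (a uracil glycosylase), -0.28 for Ifngr1, -0.16 for Il17ra and 0.34 for Il4ra. In simulated data the same test recovered 13.4% of 1.5-fold, 59.7% of 2-fold and 93.9% of 4-fold changes, so changes of 1.5-fold were mostly missed.

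Of 21 gene lists with at least 5 tested members in GC B-like cells, 11 changed by limma's camera test with a preset correlation, and none kept an adjusted p under 0.05 with an estimated correlation. The interferon gamma response list had the lowest p: 20 of its 21 members had positive fold changes (median log2 0.36, adjusted p = 1.7e-06; adjusted p = 0.594 with an estimated correlation). The interferon-inducible GTPases Irgm1 (1.30) and Gbp8 (1.68) were among them, and 5 members passed when adjusted over the list alone, 0 over all genes. Glycolysis genes rose in the same cells, with 16 of 16 positive (median 0.26, adjusted p = 1.76e-06; adjusted p = 0.594 with an estimated correlation). Among them Gapdh (0.64), Eno1 (0.62) and Hk2 (0.80) were 3 of 6 that passed adjusted over the list alone, and 0 passed over all genes. The mitotic G2 and M phase list fell, with 19 of 20 negative (median -0.23, adjusted p = 5.7e-06; adjusted p = 0.594 with an estimated correlation), among them Aurkb (-0.35) and Cdk1 (-0.34), with 0 members past either adjustment. T cell transcripts moved with these lists: the T cell marker list, 5 genes among them Cd3e (1.57) and Trac (1.00), was higher in p19-/- GC B-like cells (adjusted p = 0.00316; adjusted p = 0.594 with an estimated correlation).

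Among the other 7 called lists, base excision repair genes (25 tested, 17 negative, adjusted p = 0.0351) fell; the alkyladenine glycosylase Mpg (-0.61) and Neil3 (-0.50) passed adjusted over the list alone, and 0 passed over all genes. The dark zone list (12 tested, 11 negative, adjusted p = 0.0164) and the S phase list (20 tested, 16 negative, adjusted p = 0.0215) were lower, and the light zone list (16 tested, 15 positive, adjusted p = 0.0351) higher, with Myc at 0.65 and Icam1 at 0.34. Several lists share genes, so their calls are not independent. Hmmr, Ccnb1, Ccnb2, Aurka and Cdc20 are in both the dark zone and the G2 and M phase lists. Pcna and Fen1 are in both the base excision repair and S phase lists. Nfkbia, Icam1 and Traf1 are in both the light zone and the NF-kB and IL-17 response lists. NF-kB and IL-17 response genes were higher (19 tested, 18 positive, adjusted p = 0.0265), as were immediate early and heat shock genes (15 tested, 13 positive, adjusted p = 0.0215), among them the chaperone Hsph1 (1.31). T cell activation genes were higher too (11 tested, adjusted p = 0.0163), among them Izumo1r (1.88), Lag3 (1.76), Tigit (1.46) and, with the lowest p, Nfatc1 (0.57), beside the T cell markers given above. With an estimated correlation adjusted p was 0.675 for S phase and 0.594 for the other 6. Without p19-/- 1, 5 lists were called, all among the 11; without p19-/- 3, 7 were called, 6 of them among the 11.

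Switching machinery and cytokine receptors did not pass as lists in GC B-like cells. The class-switch recombination machinery list (27 tested) had 12 positive and 15 negative members, a median of -0.01 and a mean of 0.01, and the test's direction was down (adjusted p = 0.664). Cytokine receptors of B cells (20 tested, 13 positive) gave adjusted p = 0.136; Il9r, the IL-9 receptor (3.01), passed adjusted over the list alone (0.0144) but not over all genes (0.252). Adjusted p was 0.496 each for type I interferon response, memory B, MHC class II presentation and B cell receptor signalling, 0.249 each for plasma cell and oxidative phosphorylation, 0.679 for Tfh and 0.208 for B cell marker genes. The memory B list had a median of -0.08, a mean of 0.22 and a test direction of down.

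Mature non-GC B-like cells gave 6 of 7510 genes. Stab2 was again at 0 UMIs in the 3 p19-/- mice (45.7 ± 10.0 CPM in WT, at least 42.4-fold lower, edgeR adjusted p = 0.0321). Il9r (chromosome 11, 32187544 to 32205283), the receptor for the T cell cytokine IL-9, was higher, at 34.6 ± 11.1 against 1.49 ± 0.925 CPM (log2 fold change 4.43, SE 0.567, adjusted p = 0.0455). The rest were the immunoglobulin segments Igkv5-39 (higher), Igkv5-48 and Ighv1-81 (lower) and the unnamed gene 1500011B03Rik (lower), which fell outside the naming rule and were added after their values were seen. Here 367 genes had an unadjusted p under 0.05. G2 and M phase genes were lower in 20 of 20 cases (adjusted p = 0.00320 by camera), and glycolysis (12 of 13 positive, adjusted p = 0.00578) and immediate early and heat shock genes (13 of 14 positive, adjusted p = 0.00378) higher; adjusted p = 0.795 for each with an estimated correlation. The gene count was 1 without p19-/- 1, 0 without p19-/- 2, 10 without p19-/- 3, 12 without WT 1 and 3 without WT 2, and 2 with doublets kept. Called in one B class and not the other does not show a different response; an interaction test called 3 genes, all immunoglobulin segments, so for no other gene was a difference between the B classes detected. It called 9, 1 and 8 genes without p19-/- 1, 2 and 3, and 19 and 6 without WT 1 and WT 2.

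In CD4 T-like cells, which pool Tfh-like, Treg-like and other CD4 T-like clusters, 27 genes were higher and 21 lower in p19-/- out of 10179, and in all 48 the libraries did not overlap. Spp1, which encodes the secreted phosphoprotein osteopontin (chromosome 5, 104435111 to 104441053), was at 388 ± 91.3 CPM in p19-/- and 0 UMIs in WT, at least 822-fold higher (edgeR adjusted p = 1.57e-06). A pair of guanylate-binding protein genes close to it moved apart: Gbp8 (105012513 to 105053609) rose from 4.58 ± 2.50 to 39.9 ± 7.78 CPM (log2 fold change 3.05, adjusted p = 0.00177), and Gbp9 (105076464 to 105110357) fell from 76.6 ± 11.7 to 30.2 ± 8.32 CPM (-1.38, adjusted p = 0.0106). Stab2 fell from 82.3 ± 9.33 to 0.203 ± 0.352 CPM, with 1 UMI in the p19-/- mice. Higher as well were the chaperone genes Hspb1 (2.89) and Hsph1 (1.88), the HSP90 co-chaperones Ahsa2 (1.64) and Stip1 (1.20), and Hspa8, which rose from 1195 ± 304 to 2521 ± 397 CPM (adjusted p = 0.0217). Also higher were Lman2l (1.51), the JAK-STAT inhibitor Socs3 (1.18), the collagen prolyl hydroxylase subunit P4ha1 (1.17) and the inhibitory receptor Lag3 (0.83, adjusted p = 0.0106).

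Lower in p19-/- CD4 T-like cells were Mpg, which excises alkylated bases (64.5 ± 0.609 to 26.4 ± 3.58 CPM, log2 fold change -1.30, edgeR adjusted p = 0.0034), Rassf3 (-1.53), the carboxylesterase Ces2c (-1.05), Uhrf1bp1l (-0.92), the apolipoprotein Apoc4 (-0.82), the cold-inducible RNA-binding protein Cirbp (-0.77) and Hint1 (-0.64). Hbb-bs (-3.24, edgeR adjusted p = 0.0095) and Hba-a1 (-3.15, edgeR adjusted p = 0.0399), the tested members of the erythroid marker list, were lower too. In WT 2 a single cell held 120 of the 124 Hbb-bs UMIs and a single cell 60 of the 64 Hba-a1 UMIs, so its level says little about the class. In WT 1 the 67 Hbb-bs UMIs were spread over 50 cells and the 38 Hba-a1 UMIs over 31. Whether these UMIs came from the T-like cells themselves was not tested. Ighg2c, a B cell transcript, had the lowest p among the key genes in these cells (-4.17, adjusted p = 0.0825). The gene count was 25, 79 and 24 without p19-/- 1, 2 and 3, 19 and 18 without WT 1 and WT 2, and 20 with sex as a covariate.

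In CD4 T-like cells 10 gene lists changed by camera, and none passed with an estimated correlation. Glycolysis was the clearest, with 15 of 16 members positive (adjusted p = 5.47e-05; adjusted p = 0.611 with an estimated correlation); Gapdh (0.67) and Eno1 (0.63) passed over all genes, and 5 members adjusted over the list alone. The Tfh list rose, with 14 of 16 positive (adjusted p = 0.000762; adjusted p = 0.583 with an estimated correlation). Its helper cytokine Il21 (0.51), Maf (0.33), Ascl2 (0.33) and Sostdc1 (0.41) passed adjusted over the list alone, and 0 passed over all genes. Within Tfh-like cells alone the Tfh list was not called (camera's adjusted p = 0.0551). Its rise in the pooled class may thus partly reflect the mix of clusters, which was not tested. The Th17 list was lower by camera, with 6 of 7 negative (adjusted p = 0.0167, and 0.583 with an estimated correlation). Ccr6, a chemokine receptor gene, was at 3.33 ± 2.72 against 15.9 ± 4.46 CPM (-2.44). It was the only member past the limit by edgeR adjusted over the list alone (0.00407), and did not pass over all genes (0.0872). In Treg-like cells, a part of this class, Ccr6 was called lower over all genes. No Th17 cluster was defined, so the fall need not lie in Th17 cells.

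Of the other 7 lists in CD4 T-like cells, 3 were lower: G2 and M phase (20 of 20 negative, adjusted p = 0.000762), S phase (17 of 20 negative, adjusted p = 0.0167) and type I interferon response (15 of 19 negative, adjusted p = 0.0474). The fall in cell cycle genes was not seen within the Tfh-like and Treg-like parts of this class: in Tfh-like cells 16 of 16 S phase genes and 6 of 8 G2 and M phase genes were positive, and in Treg-like cells 8 of 16 and 3 of 5. The pooled class also held 23, 25 and 45 other CD4 T-like cells in p19-/- against 98 and 49 in WT, which were not tested alone. Higher were immediate early and heat shock (11 of 13 positive, adjusted p = 0.00345), interferon gamma response (18 of 22, adjusted p = 0.0271) and T cell activation (10 of 14, adjusted p = 0.0271). Adjusted p = 0.583 with an estimated correlation for T cell activation and 0.633 for the other 5. Markers of myeloid cells moved with these lists, 6 of 7 positive (C1qb at 6.96 ± 0.855 against 3.84 ± 0.538 CPM, adjusted p = 0.0271 for the list; adjusted p = 0.611 with an estimated correlation). Not called were Th1 (0.389), Treg (0.713), naive T (0.683), NF-kB and IL-17 response (0.161), MHC class II presentation (0.131), base excision repair (0.491), class-switch recombination machinery (0.713) and cytokine receptors (0.683), as camera's adjusted p.

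Tfh-like cells, analysed alone, gave 31 higher and 22 lower genes of 9014, with no overlap of the libraries for 52 of the 53. Spp1 was strongest, with 921, 479 and 1024 UMIs in the p19-/- mice (594 ± 133 CPM) and 0 in both WT mice, at least 688-fold higher (edgeR adjusted p = 6.26e-08). Gbp8 rose from 1.69 ± 0.539 to 39.5 ± 4.60 CPM (log2 fold change 4.43, SE 0.344, adjusted p = 2.61e-05) and Gbp9 fell (-1.40). The chaperone genes Hspb1 (4.80), Hsph1 (1.91) and Hsp90aa1 (1.42, from 294 ± 30.3 to 787 ± 228 CPM) were higher, as were Socs3 (1.70) and the ubiquitin ligase Trim65 (1.36). Stab2 fell from 94.2 ± 13.5 to 0.309 ± 0.536 CPM, and Mpg (-1.37), the relaxin gene Rln3 (-2.02), Krt83 (-1.49), Ces2c (-1.12) and Cd22, an inhibitory lectin of B cells (-1.11, 45.7 ± 8.0 to 21.1 ± 2.23 CPM), were lower. Hbb-bs fell by edgeR from 46.5 ± 22.2 to 2.92 ± 3.57 CPM (-3.94), with all 120 UMIs of WT 2 in 1 cell and the 47 of WT 1 spread over 32 cells. The count was 17 without p19-/- 3, 32 without WT 1, 18 without WT 2 and 23 with sex as a covariate.

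Of the Tfh list none passed over all genes: Bcl6, the master regulator of the lineage, differed by 0.05 and Cxcr5, its follicle-homing receptor, by 0.01 on the log2 scale (edgeR adjusted p = 0.944 and 0.994). Ifngr1 was at -0.65 (adjusted p = 0.327). The Tfh list itself was not called, with 13 of 16 members positive (median 0.16, direction up, camera's adjusted p = 0.0551), and Maf (0.42) passed adjusted over the list alone. Camera called 3 lists: S phase (16 of 16 positive, adjusted p = 0.000595), opposite in direction to the whole CD4 T-like class, immediate early and heat shock (13 of 13, adjusted p = 0.00388) and glycolysis (12 of 14, adjusted p = 0.0215; Gapdh at 0.62). Each had adjusted p = 0.953 with an estimated correlation.

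**Figure D2:**
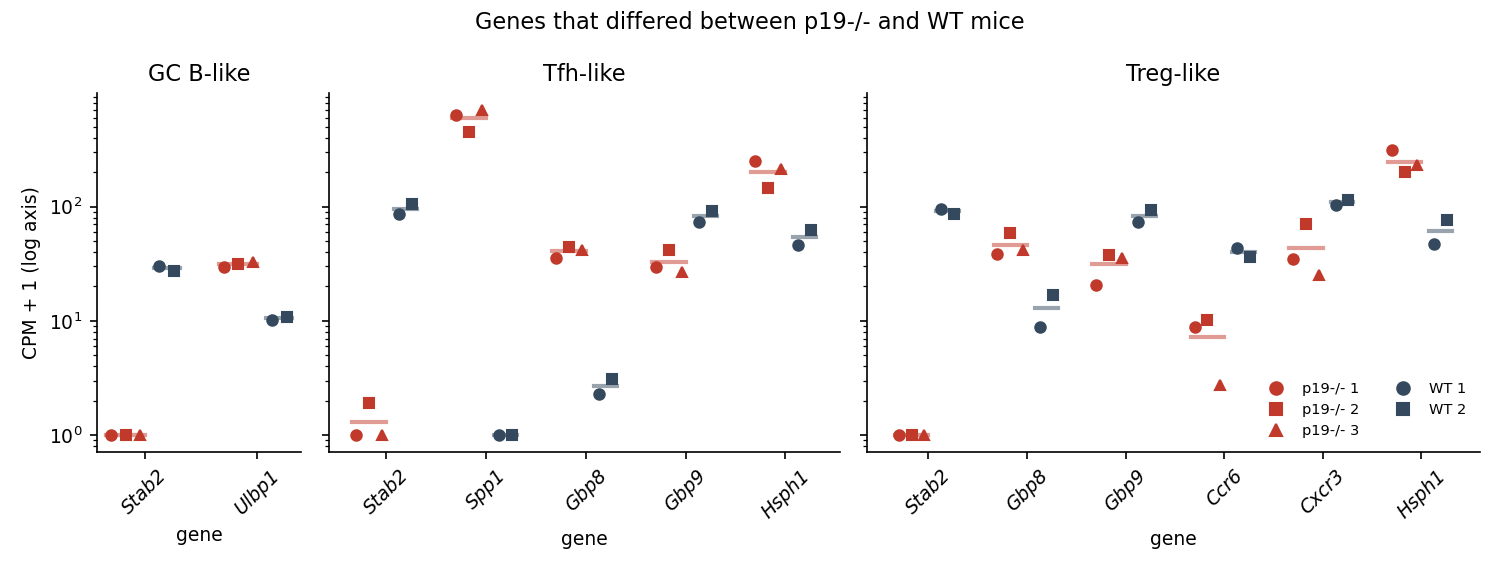
CPM plus 1 (vertical log axis) of genes that differed (horizontal axis) in GC B-like, Tfh-like and Treg-like cells; points are mice, p19-/- in red and WT in blue-grey, and short lines are group means. Stab2 is at 0 CPM in the 3 p19-/- mice in GC B-like and Treg-like cells, and Spp1 at 0 in both WT mice in Tfh-like cells against a p19-/- mean of 594 CPM.

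Treg-like cells, a class compared only after the data were seen, gave 36 higher and 18 lower genes of 7898, and in all 54 the libraries did not overlap. Lower were Ccr6, from 38.8 ± 4.87 to 6.28 ± 3.99 CPM (log2 fold change -2.93, edgeR adjusted p = 0.00265), Cxcr3 from 108 ± 8.41 to 42.3 ± 23.6 CPM (-1.53, adjusted p = 0.00773) and Ccr7 (-2.03), each a chemokine receptor gene. Ebi3, a subunit shared by IL-27 and IL-35, fell from 60.4 ± 11.7 to 24.4 ± 0.812 CPM (-1.28), and the fatty acid-binding protein Fabp5 (-1.22), Actg2 (-2.09), Mpg (-1.48), Gbp9 (-1.41) and Ces2c (-1.15) were lower. Stab2 was at 0 UMIs against 89.7 ± 5.73 CPM, at least 63.4-fold lower. Higher were Sncg (3.07), the lubricin gene Prg4 (2.24), the transcription factor Klf5 (1.42), the mitophagy receptor Bnip3 (1.23), Lag3 (1.00), Gbp8 (1.81), Lman2l (1.54) and the chaperones Hspb1 (2.85), Hsph1 (1.99), Stip1 (1.24) and Ahsa2. Spp1 was low, at 15.3, 4.57 and 5.01 CPM against 0 and 0. The count was 21 without WT 1 and 34 with DESeq2's Wald test.

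Camera called 6 lists in Treg-like cells, all higher in p19-/-. Glycolysis had 14 of 14 members positive (adjusted p = 7.15e-09; adjusted p = 0.452 with an estimated correlation), with 13 past 0.05 adjusted over the list alone and Gapdh (0.78) and Eno1 (0.79) over all genes. T cell activation (adjusted p = 0.0257; adjusted p = 0.782 with an estimated correlation) rose, as did interferon gamma response (0.0281), immediate early and heat shock (0.0334), NF-kB and IL-17 response (0.0369) and MHC class II presentation (0.0369), each with adjusted p = 0.788 with an estimated correlation. The class II genes H2-Ab1 (1.03) and H2-Aa (1.12), normally products of antigen-presenting cells, passed adjusted over the list alone and not over all genes. Lists of B cell genes were not called: 3 of 4 B cell markers (too few for the test; median log2 fold change 0.63), 6 of 6 plasma cell genes (0.55, adjusted p = 0.168) and 8 of 10 B cell receptor signalling genes (0.26, adjusted p = 0.129) were positive, 3 of the last (Lyn, Pik3cd and Ptpn6) passed adjusted over the list alone, and Cd79a stood at 61.1, 2.29 and 15.0 CPM against 13.0 and 9.28.

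Tfh-like and Treg-like cells shared 24 changed genes, all in the same direction; 18 were higher, where unrelated lists would share 0.122, and the rest lower, where they would share 0.0324. Part of this may come from the mice themselves, since both classes were taken from the same 5 animals. Stab2, Gbp8, Gbp9, Mpg, Lman2l, Ces2c, Hsph1, Hspa8 and Stip1 were among the 24, and Spp1 was not. GC B-like cells shared only Stab2 with each of the other classes. The overlap of 35 genes between CD4 T-like and Tfh-like cells is built in, since the first includes the second. Of 60 changed genes with coordinates in the 4 planned classes, 10 lay on chromosome 11, 9 on chromosome 10 and 8 on chromosome 5, where 5.08, 2.91 and 3.81 would fall by the number of genes tested.

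**Figure D3:**
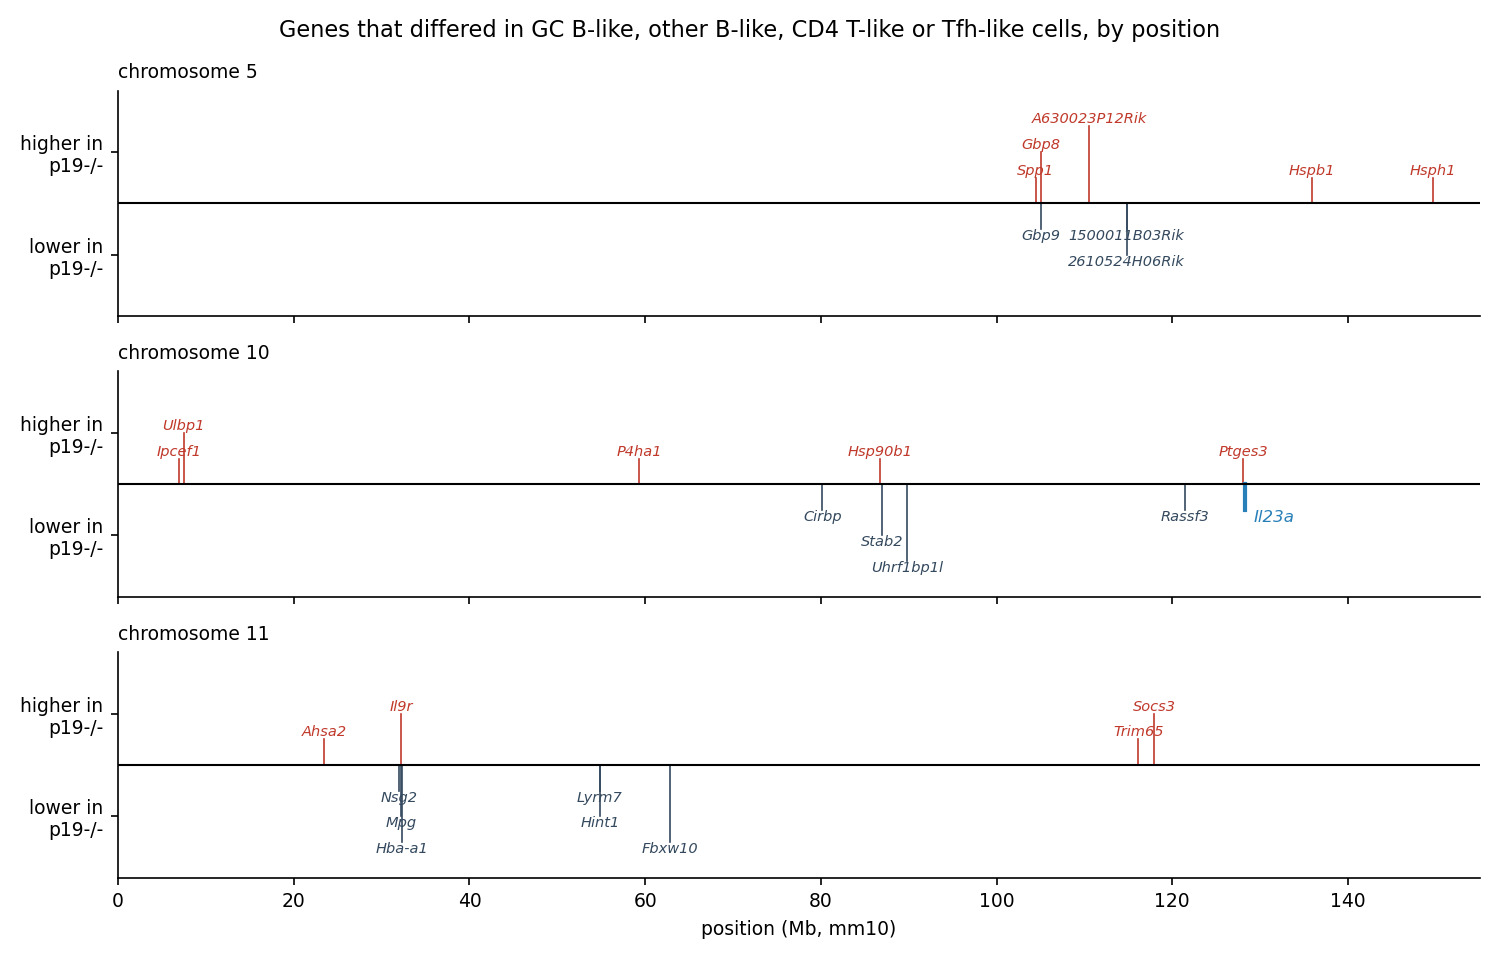
Positions (Mb, mm10, horizontal axis) of genes that differed in any of the 4 planned classes on chromosomes 5, 10 and 11, drawn upward in red where higher in p19-/- and downward in blue-grey where lower; heights carry no value, and Il23a is marked in blue. Spp1, Gbp8 and Gbp9 lie together on chromosome 5, Il9r, Mpg and Hba-a1 on chromosome 11, and on chromosome 10 Ptges3 (128058982 to 128077254) lies near Il23a (128296140 to 128298084) and Stab2 apart from it.

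Within GC B-like cells, cytokine receptors and DNA repair enzymes were split between zones. The cells with the highest and lowest dark minus light zone scores of each mouse (965 cells each, from 2899) were compared with mouse as a block, and 2602 of 8835 genes differed, 1267 higher in dark-zone-like and 1335 in light-zone-like cells. Higher at the dark end were Neil1 (509 ± 99.4 against 222 ± 68.7 CPM, log2 fold change 1.22, edgeR adjusted p = 6.06e-07), the repair scaffold Xrcc1 (0.54) and Il17ra, the IL-17 receptor (71.1 ± 4.23 against 47.5 ± 9.02 CPM, 0.56, adjusted p = 0.00146). Higher at the light end were Il21r, the receptor for the Tfh cytokine IL-21 (230 ± 18.3 against 99.2 ± 8.89 CPM, -1.22, adjusted p = 1.3e-07), Il2rg (-1.15), Ifngr2 (-1.57), Il4ra (-0.69), the BAFF receptor Tnfrsf13c (-0.70), Cxcr5 (-0.77), the abasic-site endonuclease Apex1 (-0.97), Ung (-0.38) and Polb (-0.32, adjusted p = 0.0199). Each of these had the same direction in 5 of 5 mice. Not called were Ifngr1 (-0.20), Parp1 (0.08), Msh6 (-0.02) and Il6ra (-0.02); Smug1 and Il10ra had too few counts.

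Some of the wider lists leaned toward an end of the score, and others were split between the ends. No list test was run between the ends. Of 20 G2 and M phase genes 20 were higher at the dark end, and of 15 interferon gamma response genes 15 at the light end, as were 15 of 18 NF-kB and IL-17 response and 10 of 12 MHC class II genes. Cytokine receptors of B cells gave 11 light and 2 dark of 16, base excision repair 6 dark and 4 light of 23, and switching machinery 4 dark and 5 light of 27, with the end-joining ligase Lig4 (1.57) dark and the transcription factor Batf (-3.00) light; adjusted over the list alone the counts were the same. Oxidative phosphorylation gave 12 dark and 2 light of 23, and 16 and 2 adjusted over the list alone. Dark-zone-like cells had a median of 11216 UMIs and light-zone-like cells 8169, and 578 of 2899 cells lay near a limit of these ends. With cells thinned to 2000 UMIs before scoring, and the 77 of 2899 that held fewer left out, 1225 genes were called, 1175 of them among the 2602. With cell cycle genes in the dark score 2788 were called, 1574 of them among the 2602, and the called zone genes named above kept their direction, Xrcc1 (0.18) and Polb (-0.11) without a call.

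**Figure D4:**
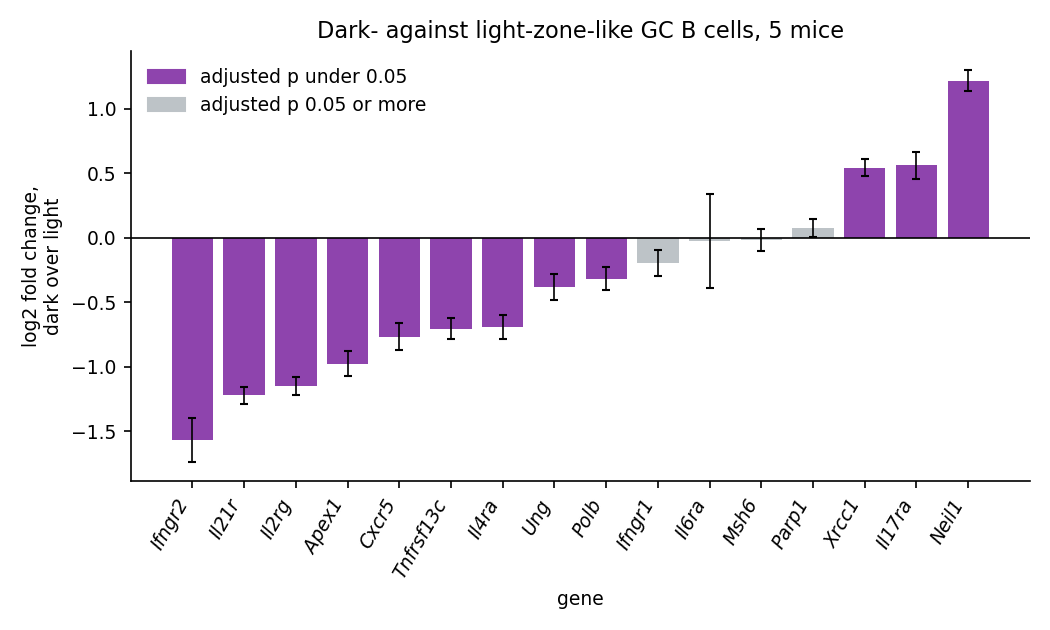
Log2 fold change of the dark over the light end of GC B-like cells (vertical axis, bars, with SE) for 16 tested genes (horizontal axis), 5 mice with mouse as a block; purple marks adjusted p under 0.05. Il21r (-1.22) and Ifngr2 (-1.57) are lower and Neil1 (1.22) and Il17ra (0.56) higher at the dark end.

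IgG2b, the isotype of the series title, made up a smaller part of class-switched GC B-like cells in each p19-/- mouse than in each WT mouse, though 3 mice against 2 cannot show this at 0.05. The shares were 20.8% (30 of 144 cells, Clopper-Pearson 95% interval 14.5 to 28.4%), 15.8% (28 of 177, 10.8 to 22.0%) and 17.2% (79 of 458, 13.9 to 21.0%) in p19-/- and 24.0% (165 of 687, 20.9 to 27.4%) and 26.0% (75 of 288, 21.1 to 31.5%) in WT. The group means were 18.0 ± 2.58% and 25.0 ± 1.43%, a difference of -7.06 percentage points (two-sided exact permutation p = 0.2, the smallest possible; 0.6 after adjustment over 6 isotypes). IgG1 was the most common isotype in p19-/-, at 50.8 ± 10.5% against 33.9 ± 2.09% (exact permutation p = 0.2), and IgG2c stood at 25.4 ± 10.4% against 36.9 ± 1.57% (exact permutation p = 0.4). IgG3 was at 4.79 ± 3.58% and 3.52 ± 2.03% (exact permutation p = 0.8), and IgA and IgE each made up under 1% on average in both groups. The class-switched share was 80.4 ± 13.6% against 81.6 ± 5.01% (exact permutation p = 1), a difference of -1.18 that was 6.58 without p19-/- 3, 2.36 without WT 1 and -4.06 with doublets kept. Counting all cells with a heavy chain, the IgG2b difference was -3.14 (exact permutation p = 0.6) and the class-switched difference -12.7 (exact permutation p = 0.4). In p19-/- 1 these include the mostly IgM clone of its unnamed B cells, with 321 of 821 barcodes, which lowers the class-switched share of that mouse. The intervals cover counting error only.

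**Figure D5:**
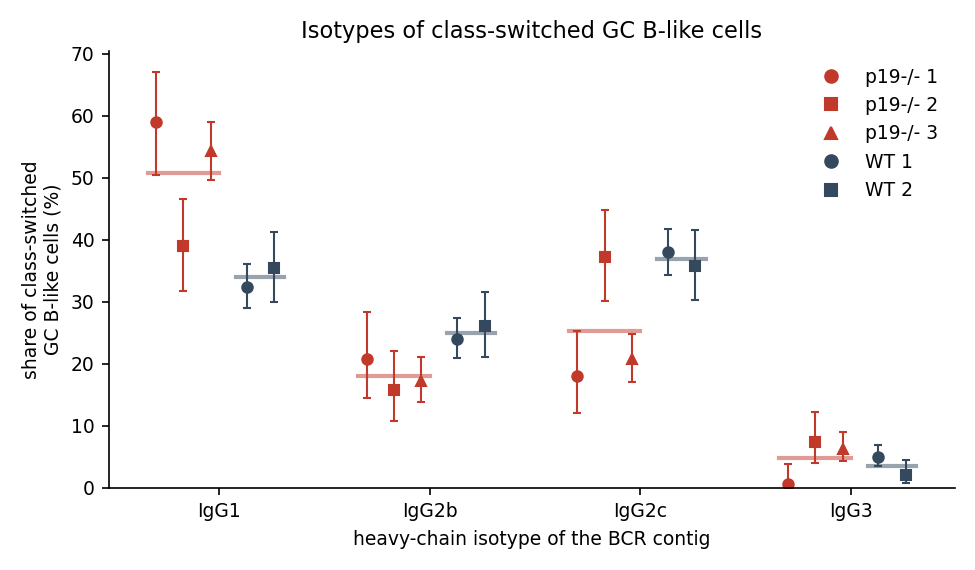
Share of class-switched GC B-like cells (%, vertical axis) with each IgG isotype (horizontal axis); points are mice, p19-/- in red and WT in blue-grey, with Clopper-Pearson 95% intervals that cover counting error only, and short lines are group means. IgG2b is at 20.8%, 15.8% and 17.2% in p19-/- and 24.0% and 26.0% in WT.

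Clonal expansion of GC B-like cells was higher in each p19-/- mouse than in each WT mouse when 160 cells were drawn per mouse. The share of cells in clones of at least 2 was 11.3%, 7.45% and 9.17% against 6.06% and 5.20%, or 9.29 ± 1.90% against 5.63 ± 0.605% (difference 3.66, two-sided exact permutation p = 0.2, the smallest possible). Without equal draws, where the number of cells recovered differs, the difference was 3.59 (exact permutation p = 0.8). With cells drawn from all those with a heavy chain it was 19.3 (exact permutation p = 0.2), with a share of 51.1% in p19-/- 1. The largest clone had 22 cells in WT 1, using IGHV1-26 and IGHJ4, with 10 IgG2b, 10 IgG2c and 2 IgM cells, and the next had 13 cells in p19-/- 3 and in WT 2. Of 6, 8 and 52 expanded clones in p19-/- and 33 and 8 in WT, 1, 0, 12, 9 and 1 held more than 1 isotype. A heavy chain was found in 70.8%, 84.0% and 79.3% of p19-/- and 75.8% and 77.8% of WT GC B-like cells. In T-like cells, which should lack one, the shares were 6.18%, 2.06%, 1.27%, 0.977% and 0.701%; in p19-/- 1, 25 of these 41 T-like cells carried 1 clone, that of its unnamed B cells.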

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

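All artifact tests in this part were chosen only after the result they bear on was seen; the tests behind the values themselves were planned, apart from the comparison of Treg-like cells, and the limits for doublets and free RNA in the second pattern were set with their values in view.

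The difference between the mouse groups was not the same in GC B-like and mature non-GC B-like cells, by the interaction test in edgeR, for the immunoglobulin segments Igkv14-126 (a difference of 8.43 on the log2 scale, adjusted p = 0.00725), Igkv9-123 (13.21, adjusted p = 0.0471) and Ighv1-81 (2.59, adjusted p = 0.0471). Which clones carried these segments was not examined, so the clones that single mice happened to hold cannot be told apart from genotype here. Unnamed B clusters, whose genes were not compared between genotypes, held 19.3% of the cells of p19-/- 1 and 6.46% of those of p19-/- 2, against 0.173% in p19-/- 3, 0.293% in WT 1 and 0.778% in WT 2. Barcodes over the mitochondrial limit, which were not used, were 36.0% in p19-/- 1 against 9.17 to 13.2% in the other 4 RNA libraries.

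The first pattern is that Stab2 and neighbouring pairs of genes differed in many cell classes at once. Stab2 RNA carried over from macrophage-like cells is argued against: WT Tfh-like cells had 0.485 of the CPM of WT macrophage-like cells, where the abundant C1q genes of those cells reached at most 0.00302, and p19-/- macrophage-like cells kept 167 CPM of Stab2 while p19-/- Tfh-like cells had almost none. With sex as a covariate, where the genotype effect rests on the females, 20 of the 53 genes called in Tfh-like cells were called again in the same direction, among them Stab2, Spp1, Gbp8 and Gbp9, which argues against the sex of p19-/- 3 for these; for the other 33 it stays open. A candidate explanation is that stretches of chromosome differ between the mouse groups, through strain DNA that came with the p19 allele or through parental segments of the BXD2 genome. DBA/2J, a parent of BXD2, is known to carry a retroviral insertion at Stab2 that drives its expression. Ptges3, the called gene closest to Il23a, lies on chromosome 10 at 128058982 against 128296140. However, Ptges3 was called in the same T cell classes as Hsph1, Stip1 and Hspa8, so its call may belong to the heat shock pattern below. Of 60 called genes 23 lay within 2000000 bases of another against a random mean of 9.57 (permutation p = 0.0014), but with close neighbours merged it was 14 against 8.76 (permutation p = 0.111). Differing stretches of chromosome thus stay open as an explanation, as does an effect of IL-23 itself.

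The second pattern is a B cell population of nearly 1 clone in p19-/- 1. Of 222 of its unnamed B cells with a heavy chain, 215 shared IGHV1-80, IGHJ4 and 1 CDR3, and 208 of these 215 were IgM. Free RNA of the clone is argued against, since 72.1% of all 298 cells carried its heavy chain against 3.77% of 663 T-like and 0.442% of 226 GC B-like cells of that mouse, and so are cells carried over from another library of the series, since 0 barcodes of the clone were found in the other 4, against 321 in its own. Doublets as the source of the population are argued against too: 0 of the 222 cells had 2 or more heavy chains, 5.37% of the 298 held a UMI of T cell markers (99.7% of T-like cells) and 32.9% a UMI of myeloid markers (99.1% of macrophage-like cells). The cells may be an expanded B cell clone of that animal, as a hypothesis, and no biological explanation was tested. In p19-/- 2 the unnamed B cells had a different leading clone (9 of 15 cells). Of the population's leading genes, Scd1 was lower there than in WT mature non-GC B-like cells (57.9 against 106 CPM). Sox4 was at 0 against 7.82 CPM, but these 61 cells held only 103691 UMIs, so a level like that of WT could be missed. The other leading genes were higher, among them Plac8 (1254 against 175 CPM) and Fcrl5 (96.4 against 26.2 CPM). The lowest of these, such as Alpl at 9.64 CPM, rest on almost no counts.

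The third pattern is that the heat shock members of a tested list were higher in p19-/- mice in several classes. Poor quality of the library p19-/- 1 is argued against in CD4 T-like cells, where the median log2 fold change of the heat shock members was 1.03 without it and 1.22 with it. In GC B-like cells it may account for part, since that median went from 0.919 to 0.451. In CD4 T-like and Tfh-like cells a general dissociation response that raises the immediate early members about as much is argued against. The heat shock medians there rest on 3 members each, at 1.22 (SD 0.680) and 1.42 (SD 0.666). Elsewhere the spreads of heat shock and immediate early members overlapped, so such a response stays open. The heat shock SD was 0.955 over 4 members in GC B-like, 0.738 over 3 in Treg-like and 0.567 over 3 in mature non-GC B-like cells. Handling that raises the heat shock members alone is not addressed by this comparison. The median of the immediate early members was 0.13 (SD 0.391) in CD4 T-like, 0.11 (SD 0.224) in GC B-like, 0.17 (SD 0.414) in Tfh-like and 0.18 (SD 0.532) in Treg-like cells. A weaker dissociation response stays open, since 8 of 10, 9 of 11, 10 of 10 and 7 of 10 of these members were above 0 in these classes. In mature non-GC B-like cells their median was 0.39 (SD 0.354) and that of the heat shock members 0.66. The labels give no capture day, so a difference in handling between the groups stays open, as does genotype.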

How the results depend on the processing

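The clusters without called genes, the B cell share without unnamed clusters the Treg-like class and unnamed T cluster with their alternatives, and the exchange of zone sums within mice were chosen after seeing the data; all other tests in this part were planned. With 3 mice against 2, depth and spread leave most 1.5-fold changes undetected. Where 1 WT mouse was left, the lone sample is assumed to vary like the others. Unless a reason is given below, the cause was not tested. Named genes that were called kept direction and call in 637 cases and only direction in 70 over the alternatives that keep all mice, and in 240 and 145 without 1 mouse; none reversed. For list calls the numbers were 33 and 51, and 73 and 31 without 1 mouse. The zone genes kept their call in 127 cases and only direction in 8, and 1 reversed, at -0.30, with cell cycle genes in the dark score.

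Gene counts in GC B-like cells (2 in the report) were 48 with DESeq2's Wald test and 22 without immunoglobulin genes. Without the low-count filter they were 292 in GC B-like, 143 in mature non-GC B-like (6 in the report), 323 in CD4 T-like (48), 238 in Tfh-like (53), 162 in Treg-like cells (54) and 89 in the unnamed T cluster (18). With sex as a covariate, which compares 2 female p19-/- with 2 WT mice, they were 8, 10, 20 and 23 in the first 4 classes and 36 in the unnamed T cluster. In mature non-GC B-like cells they were 2 with doublets kept and 3 for clusters without called genes; in Treg-like cells DESeq2's Wald test gave 34. The interaction gave 1 gene with DESeq2 size factors, and thinning gave 1225 zone genes. Of the gene lists, 0 were called with an estimated correlation in GC B-like and in CD4 T-like cells, and fry called 2 and 0.

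Without 1 mouse, gene counts ranged from 0 to 10 in GC B-like, 0 to 12 in mature non-GC B-like, 18 to 79 in CD4 T-like, 17 to 48 in Tfh-like 21 to 73 in Treg-like cells and 11 to 28 in the unnamed T cluster, 1 to 19 for the interaction and 1957 to 2394 for zones, and list calls from 5 to 12 in GC B-like and 7 to 8 in CD4 T-like cells. The IgG2b difference ranged from -8.50 to -5.99, the GC share from -24.8 to -6.53, the expanded share from 3.23 to 4.47, and the class-switched share from -5.98 to 6.58; it was 6.58 without p19-/- 3 and 2.36 without WT 1, both reversed.

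The replicate numbers of the labels as a block gave 58, 45, 307, 28, 107 and 68 genes in these classes in the order above. Whether these numbers pair the mice could not be decided. Expression profiles, centred within groups, correlated across genes at -0.0592 (GC B-like) and 0.0535 (CD4 T-like) for mice numbered 1. For mice numbered 2 the values were 0.0386 and 0.115. With 2 WT mice, centring makes the profiles of WT 1 and WT 2 mirror images, so these values carry little information.

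For the zone comparison, the 16 ways of exchanging the zone sums within mice are too few for a share under 0.05; the real assignment gave 2602 genes and the highest other 1.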

Other observations

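Apart from the zone comparison, which was planned, the values in this part were chosen only after the results were seen.

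Outside the tested classes, CD8 T-like cells resembled the CD4 T-like cells in a few genes. Hspa8, a constitutive chaperone, stood at 2652, 2310 and 2434 CPM in p19-/- CD8 T-like cells against 1033 and 1140 in WT, and Stab2 at 61.0 and 60.9 CPM in the WT mice. Plasma cells of the WT mice had 23.2 and 24.2 CPM of Stab2. An unnamed T cluster, compared after the data were seen, gave 18 changed genes of 5416 in edgeR, 16 higher and the rest lower. Spp1 was higher there, at 629, 286 and 806 CPM against 19.3 and 14.8 (log2 fold change 5.04, adjusted p = 1.22e-05), as were Gbp8 (2.45) and Hsph1 (2.13), and Stab2 was lower (adjusted p = 9.9e-05). The count was 11 without p19-/- 1 or without WT 1 and 28 without p19-/- 3. In GC B-like cells Spp1 was at most 0.278 CPM in any mouse. Over whole libraries Spp1 stood at 118, 85.3 and 86.4 CPM in p19-/- and 0.635 and 0.845 in WT, and Ifng at 14.7, 9.85 and 6.69 against 4.44 and 6.37.

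Zone genes with the largest fold changes included Rgcc (1.89), Emp2 (2.01) and the Argonaute gene Ago4 (2.14) in dark-zone-like cells, and Slfn2 (-5.31), the cyclin Ccnd2 (-4.97), the activation factor Egr2 (-3.15) and the IgE receptor Fcer2a (-2.97) in light-zone-like cells, each in 5 of 5 mice by edgeR. Among the barcodes of p19-/- 1 that failed the filters, 209 had a heavy chain and 24 of these (11.5%) shared 1 clone with IGHV1-80 and IGHJ4, of isotype IgG2b and found in 5 GC B-like cells of that mouse too; its CDR3 differed from that of the IgM clone of the unnamed B cells, which 22 of the 209 carried.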
